A study of Oryza sativa with 18 samples.

How the data were processed

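Transcript levels were measured in rice stems at the tillering stage with one-colour Affymetrix arrays, and 18 arrays were analysed. Per the labels' protocols, plants of Rathu Heenati (RHT, resistant to the brown planthopper) and Taichung Native 1 (TN1, sensitive) grew under 14 h of light at 28 °C and 10 h of dark at 23 °C. Each plant received 10 nymphs of the 2nd to 3rd instar, and stems were taken after 0, 8 and 24 h. Biotin-labelled cRNA was made from 6 ug of total RNA, per the labels' protocols. The 6 groups hold 3 biological replicates each, and group and replicate number were taken from the sample titles.

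The deposited values are on the log2 scale, and the submitters' processing notes name MAS5, with the version not given in the sources used here. MAS5 summarises the probes of a probe set into a signal and scales each array. A trimmed mean that leaves out 2% of the probe sets at each end was 500.1 on the linear scale on every array, so the deposited log2 values carry a common scaling and no further normalization was applied. The lowest value was 0 and held 1.1% to 3.02% of the probe sets of an array. For arrays, the number of arrays limits the precision. The deposited file gives no detection calls, so 17 reporter-tag probe sets that match no rice transcript gave the background: their highest value per array lay between 4.88 and 6.09 log2 units. Where a probe set lay below that value on every array of a group, or on some of them, the report gives a bound ("at least"): the mean of the brighter group against the mean of the dimmer group with each array raised to its own highest tag. The p beside a bound comes from the fit to the deposited values. The bounds were added after seeing the data, and fitted counts and correlations use the deposited values. A list median given once was the same with values raised in this way.

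The file holds 57381 probe sets, of which 123 are controls. Of the 57258 rice probe sets, 22436 name 1 gene in the platform annotation, 95 name several and 34727 are unnamed here. All 17905 genes named in this way matched the reference gene table of assembly ASM3414082v1 by gene identifier, and 2448 carry a published name there. The array's own build is not given in the sources used here, so the table served only for names and for the order of neighbouring genes.

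Tests were run in R 4.3.3 with limma 3.58.1, with data.table (version 1.17.8) and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Control probe sets were left out, and a rice probe set was kept when it lay above the array median in at least 3 of the 18 arrays, which left 34346. A model with a mean for each group was fitted over all 18 arrays with lmFit, followed by eBayes with a trend of the variance on the mean. Benjamini-Hochberg adjustment was applied within each of 9 comparisons, and a probe set was called at an adjusted p under 0.05. The comparisons were 8 h and 24 h against 0 h in each variety, RHT against TN1 at each time, and the difference between the varieties' responses at 8 h and at 24 h (the interaction). Values after ± are standard errors of this fit unless SD is given, except in the closing section for ratios and the actin slope. There the error of a ratio is a jackknife standard error, from leaving out each of the 18 arrays in turn. The error of the actin slope comes from a linear regression.

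Gene lists were tested with camera at a preset correlation of 0.01 between genes, with 1 probe set per gene (the highest mean value), and adjusted over all 189 pairs of list and comparison. The themes of 30 lists were fixed before the data were examined. Their members were translated to the symbols of the reference table after that table was opened and before any expression value was tested. Of the 30 lists 22 found members and 21 had at least 4 measured genes. Each list was tested again with the correlation estimated from the data. Counts "adjusted over the list alone" repeat the adjustment within the members of a list.

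The genes named were chosen by a rule fixed before the data were examined: per comparison, the 8 highest and the 8 lowest called genes whose arrays did not overlap between the groups (overlap was allowed for the interactions), the 3 members with the smallest p of each called list (where fewer than 3 lists were called, also of the lists with the smallest p, up to 3 lists), and the clock genes in each comparison with 0 h. The rule asked for an informative description. The annotation holds none, so a published name was required in its place. For the highest and lowest genes the probe set with the smallest p stands for the gene. The report gives a subset, mostly genes whose calls held when each array was left out. Members outside the rule are named only in the closing section, where that is stated.

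The testing steps were checked on simulated data for TN1 at 8 h, with 34346 probe sets and 200 planted changes in brighter probe sets. The simulated noise was independent between probe sets and of equal size on every array, so the recovery and false calls may not carry over to the real arrays. The fit recovered 41.8% of changes of 1 log2 unit, 89.6% of 2 and 95.5% of 3, with 5 false calls. For the interaction at 8 h the same changes were recovered at 14.9%, 67.2% and 81.8%. Alternatives fixed before the data were examined were quantile normalization, median centring, an offset before log2, 2 other filters, 2 other variance models, a replicate block, a fit to the compared arrays only, all probe sets of a gene in a list, an estimated correlation, and leaving out each array. Array quality weights and the removal of 2 arrays together were added after seeing the data. Uninfested stems at 8 h and 24 h were not analysed here.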

Results

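Stems of the brown planthopper-resistant rice variety RHT and of the sensitive variety TN1 were profiled before infestation and after 8 h and 24 h with nymphs, with 3 arrays in each of the 6 groups. Correlations between arrays of the same group over the 34346 probe sets kept ranged from 0.901 to 0.963, and between groups from 0.779 to 0.938. The first principal component held 30.9% of the variance and ran from the RHT arrays to the TN1 arrays. Apart from the lowest value, no pair of arrays shared more than 2 identical values over the probe sets kept. The 3' to 5' difference of the elongation factor control probe sets was lower at 8 h by -2.05 and at 24 h by -1.58 log2 units, averaged over the varieties (exact permutation within varieties, two-sided, adjusted p = 0.04 for each over 8 tests). The same difference for actin was 0.44 and 0.54 higher (adjusted p = 0.12 for each). Uninfested stems at 8 h and 24 h were not analysed here, so a difference from 0 h covers infestation, time of day and plant age together.

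**Figure D1:**
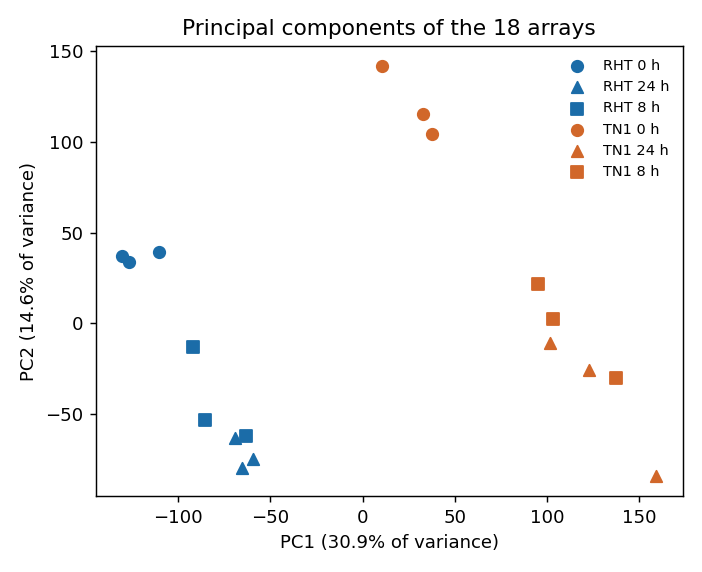
Each point is an array, placed by the first (PC1) and second (PC2) principal components of the log2 values, in arbitrary units with the percent of variance on each axis. Colour gives the variety and shape the hours of infestation; the axes hold 30.9% and 14.6% of the variance.

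In RHT after 8 h, all measured clock genes changed, and single genes with other roles were among the largest changes. PCL1, a component of the circadian clock, was not above background on any array at 0 h and at least 275-fold higher at 8 h (adjusted p = 3.48e-07). CCA1, a morning-phased clock gene, fell by 5.56 ± 0.21 log2 units (n = 3), and all 7 measured clock genes were called, 3 higher and 4 lower (3 and 4 adjusted over the list alone), including PRR1 at 1.87 ± 0.22 and GI at 1.22 ± 0.16. PRR73 was not called when RHT 0 h replicate 1, 2 or 3 or RHT 8 h replicate 2 was left out (adjusted p between 0.0831 and 0.115), nor PRR37 without RHT 8 h replicate 2 (0.0518), and the dimmer probe set of PRR73 stood at -0.23 ± 0.19 and was not called. The protein kinase gene SAPK9 rose by 5.26 ± 0.28, and the heat stress factor gene HSF03, not above background on any array at 0 h, was at least 13.2-fold higher (adjusted p = 1.69e-05). PORA, which makes protochlorophyllide oxidoreductase for chlorophyll synthesis, fell by 4.59 ± 0.51 and the ferric reductase gene FRO1 by 4.11 ± 0.34. The sugar transporter gene SWEET2B was at least 11.1-fold lower and at least 9.59-fold lower on its 2 probe sets, neither of them above background on any array at 8 h (adjusted p = 1.7e-05 and 0.000319). The beta-expansin gene EXPB2 fell by 4.31 ± 0.72.

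Of 12 measured photosynthesis genes in RHT at 8 h, 1 was called higher and 5 lower (1 and 5 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.00176, and adjusted p = 0.932 with an estimated correlation). PSAG, a photosystem I subunit gene, fell by 3.81 ± 0.27, LHCP by 2.30 ± 0.29 and RCABP69 by 1.27 ± 0.20; a dimmer PSAG probe set, not above background on any array at 0 h, was not called. Of 23 genes for cytosolic ribosomal proteins 4 were called lower and none higher (11 lower adjusted over the list alone), with a median of -0.27 (adjusted p = 0.000616, and adjusted p = 0.932 with an estimated correlation). Across all genes limma called 2595 probe sets, 1477 higher and 1118 lower, of which 1615 had a fitted change over 2-fold and 217 had a group not above background on any of its arrays while the other was. The count was 1232 and 1278 without RHT 0 h replicates 1 and 2, and 1382 and 1541 without RHT 8 h replicates 2 and 3; without RHT 8 h replicate 3 the ribosomal list was no longer called (adjusted p = 0.0648), leaving 1 list, and its mean difference of -0.31 was -0.18. Other splits of the same 6 arrays called up to 4 lists, against 2 in the real split. Each other split kept part of the real difference, here and below, so these list counts cannot measure chance.

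In TN1 after 8 h, several of the same genes changed. PCL1, not above background on any array at 0 h, was at least 244-fold higher (adjusted p = 1.06e-07), CCA1 fell by 5.50 ± 0.21, and 6 of the 7 clock genes were called, 3 higher and 3 lower (3 and 3 adjusted over the list alone). PRR37 was not called without TN1 0 h replicate 1 (adjusted p = 0.0807) or TN1 8 h replicate 1 (0.0694). SAPK9 rose by 5.41 ± 0.28. HSF03 was at least 15.8-fold higher (adjusted p = 2.88e-05) and LAC24, a laccase gene, at least 11.6-fold higher (adjusted p = 5.1e-05), each above background on 1 of the 3 arrays at 0 h. EXPB2, above background on 1 of the 3 arrays at 8 h, was at least 29.5-fold lower (adjusted p = 1.79e-05). PORA fell by 5.05 ± 0.51, FRO1 by 4.34 ± 0.34, and NAS3, which encodes a nicotianamine synthase for metal chelation, by 4.09 ± 0.29. CAO, which makes chlorophyll b, fell by 4.09 ± 0.25.

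Of the 12 photosynthesis genes in TN1 at 8 h, 7 were called lower and none higher (8 lower adjusted over the list alone), with a median of -1.01 (adjusted p = 0.000162, and adjusted p = 0.932 with an estimated correlation). PSAG fell by 3.71 ± 0.27, LHCP by 3.52 ± 0.29 and RCABP69 by 2.16 ± 0.20; the dimmer PSAG probe set was again not called. Of the 23 ribosomal protein genes 9 were called lower (11 adjusted over the list alone), with a median of -0.40 (adjusted p = 5.98e-05, and adjusted p = 0.932 with an estimated correlation); RPS26 fell by 1.37 ± 0.22 and RPL39B by 0.62 ± 0.13. Of 11 chitinase genes, whose enzymes break down chitin, 3 were called higher (5 adjusted over the list alone), with a median of 1.74 (1.49 with values raised to background), and CH16 rose by 2.91 ± 0.72; the list was not called (adjusted p = 0.135). TN1 8 h replicate 1 stood apart, with a chitinase mean of 10.20 against 7.62 and 7.60 in replicates 2 and 3, and without it the mean rise of 1.59 was 0.73. CH16 stayed called without that array, while the other 2 called genes, Cht6 (1.05, adjusted p = 0.0503) and Cht10 (1.42, adjusted p = 0.105), did not; Cht6 lost its call in 4 and Cht10 in 5 of the 6 refits. Limma called 6745 probe sets, 3630 higher and 3115 lower, with 4248 fitted changes over 2-fold and 554 with only 1 group above background. A fit to the 6 arrays compared called 3836. Without TN1 8 h replicate 2 the called lists numbered 5 instead of 2, without replicate 3 they numbered 3, and the chitinases were among them in both cases, and other splits of the same arrays called up to 7.

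**Figure D2:**
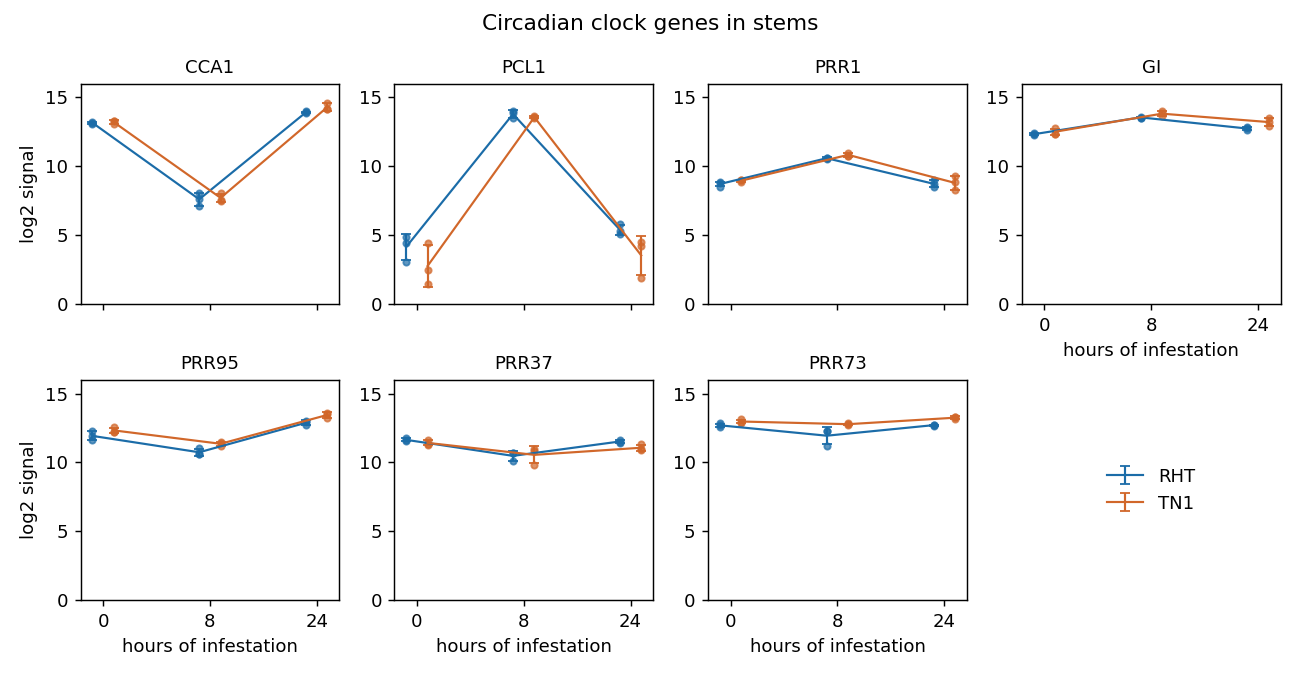
Log2 signal of 7 circadian clock genes against hours of infestation (0, 8, 24) in RHT and TN1. Points are arrays, and lines join group means with SD bars (n = 3); PCL1 was not above background on any array at 0 h in either variety; CCA1 fell at 8 h and stood at 13.93 in RHT and 14.30 in TN1 at 24 h.

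In RHT after 24 h, genes for ribosomal proteins were lower, and PBZ1 and RBTI, 2 genes linked to defence, were higher. Of the 23 ribosomal protein genes 17 were called lower and none higher (19 lower adjusted over the list alone), with a median of -0.86 (adjusted p = 1.19e-13, and adjusted p = 0.932 with an estimated correlation). RPS26 fell by 1.67 ± 0.22, RPL7A-2 by 1.28 ± 0.18 and RPL11 by 1.09 ± 0.15. PBZ1, a pathogenesis-related gene, rose by 4.67 ± 0.73, and RBTI, a Bowman-Birk trypsin inhibitor gene, by 2.94 ± 0.61. PPDK2, which encodes pyruvate phosphate dikinase, rose by 3.84 ± 0.44, while BURP2 fell by 4.42 ± 0.75 on the brighter of its probe sets and stood at -2.17 ± 0.70 on the other, which was not called (adjusted p = 0.0628). HOX10 rose by 3.00 ± 0.44 on the probe set chosen, but its brighter probe set stood at -0.08 ± 0.26.

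Of the 7 clock genes in RHT 2 were called at 24 h, both higher (3 adjusted over the list alone): PRR95 rose by 0.96 ± 0.18 and CCA1 by 0.77 ± 0.21, the latter no longer called when any of the 6 arrays was left out (adjusted p between 0.063 and 0.101). PRR1 stood at 0.02 ± 0.22 and PRR73 at 0.01 ± 0.21, and both signs turned under another scaling. Of the 12 photosynthesis genes none was called at 24 h, with a median of 0.01. Limma called 3508 probe sets, 2085 higher and 1423 lower, with 1981 fitted changes over 2-fold and 214 with only 1 group above background. The count was 1808, 1792 and 2254 without RHT 0 h replicates 1, 2 and 3, and 1700, 2260 and 2321 without RHT 24 h replicates 1, 2 and 3. Other splits of the same arrays called up to 3 lists, against 1 in the real split.

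In TN1 after 24 h, the ribosomal protein genes were again lower, and 12 of 21 genes for expansins and xyloglucan enzymes were called. Of the 23 ribosomal genes 18 were called lower and none higher (22 lower adjusted over the list alone), with a median of -1.07 (adjusted p = 2.23e-09, and adjusted p = 0.932 with an estimated correlation). RPS26 fell by 2.31 ± 0.22, RPL11 by 1.38 ± 0.15 and RPS10 by 1.21 ± 0.14. Of 21 genes for expansins and xyloglucan enzymes, which act on cell walls, 2 were called higher and 10 lower (2 and 10 adjusted over the list alone), with a median of -1.19, and the list was not called (adjusted p = 0.187). TN1 24 h replicate 1 stood apart, with a mean for this list of 8.31 against 9.28 and 9.28 in replicates 2 and 3, and without it the mean fall of 1.05 was 0.72. EXLA2 rose by 2.18 ± 0.21, while EXP10 fell by 1.25 ± 0.21 and EXP5, above background on 2 of the 3 arrays at 24 h, was at least 10.3-fold lower (adjusted p = 0.0042). PPDK2 rose by 5.34 ± 0.44, RBTI by 3.86 ± 0.61 and the laccase gene LAC7 by 3.83 ± 0.40. SWEET15, a sugar transporter gene, was at least 3.33-fold lower (adjusted p = 0.00354), and CHLI, which encodes a magnesium chelatase subunit of chlorophyll synthesis, at least 2.41-fold lower (adjusted p = 2.56e-05), each not above background on any array at 24 h. HOX10, above background on 2 of the 3 arrays at 0 h, was at least 16.3-fold higher (adjusted p = 2.13e-05), with its brighter probe set at -0.59 ± 0.26.

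Of the 7 clock genes in TN1 3 were called at 24 h, all higher on the probe set that stands for the gene (3 adjusted over the list alone), with CCA1 at 1.09 ± 0.21, PRR95 at 1.12 ± 0.18 and GI at 0.70 ± 0.16; PRR1 stood at -0.16 ± 0.22 and was not called. PRR37 stood at -0.35 ± 0.25 and was not called, while its dimmer probe set was called lower, at -0.70 ± 0.19 (adjusted p = 0.0124). Limma called 9578 probe sets, 4665 higher and 4913 lower, with 6234 fitted changes over 2-fold and 623 with only 1 group above background. Without TN1 24 h replicate 1 the count was 6339. Other splits of the same arrays called up to 6 lists, against 1 in the real split.

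**Figure D3:**
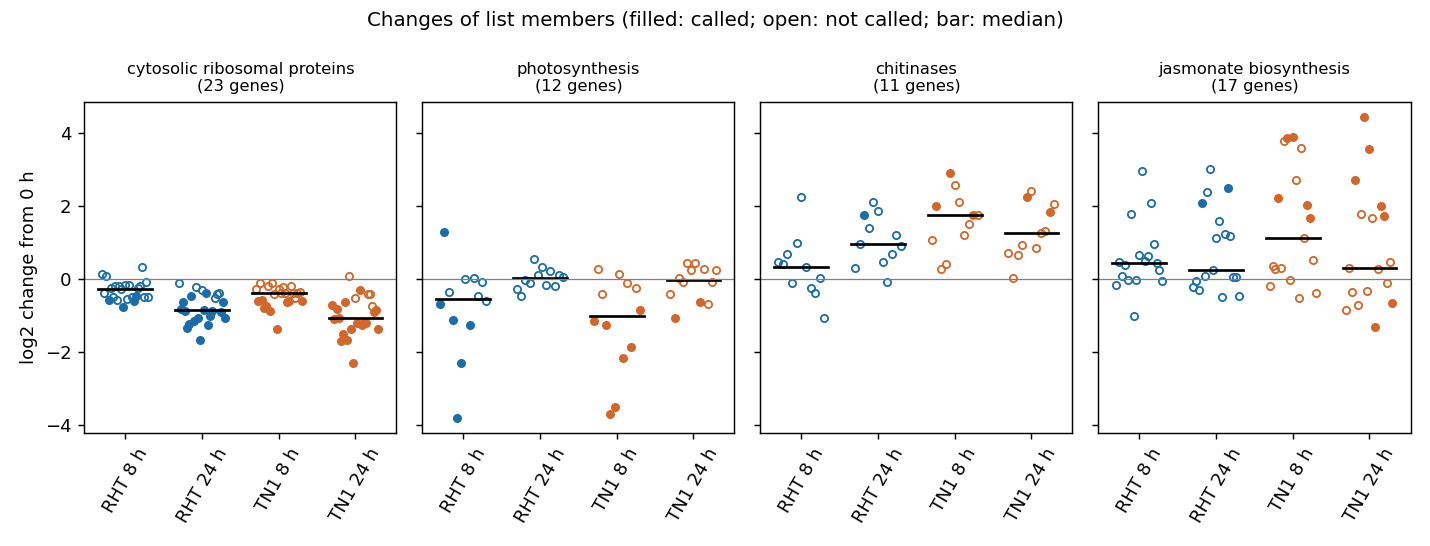
Log2 change from 0 h of each measured member of 4 gene lists (23, 12, 11 and 17 genes) in RHT and TN1 at 8 h and 24 h. Each circle is a gene, filled where called at an adjusted p under 0.05, and the bar is the median, which for ribosomal proteins was -0.86 in RHT and -1.07 in TN1 at 24 h.

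The responses of the varieties, which share no array, overlapped. Their tests do share the fitted spread of each probe set, which can raise the overlap above that of independent lists. At 8 h 1757 probe sets were called in the same direction in both, 989 higher and 768 lower, where independent lists would share 156.1 and 101.4; 5 were called in opposite directions. At 24 h 3065 were shared, 1790 higher and 1275 lower (expected 283.2 and 203.6), and 3 were opposite. Across genes, which are not independent replicates, the log2 changes of the varieties correlated at r = 0.494 (rho = 0.466) at 8 h and r = 0.646 (rho = 0.658) at 24 h. Both r were lower without a filter and higher above the 75th percentile, as the closing section gives. The shared count at 8 h was 977 and 1008 without RHT 0 h replicates 1 and 2, and 1061 and 1040 without RHT 8 h replicates 2 and 3. At 24 h it was 1643, 1638 and 1929 without RHT 0 h replicates 1, 2 and 3, and 1508 and 1956 without RHT 24 h replicates 1 and 2.

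**Figure D4:**
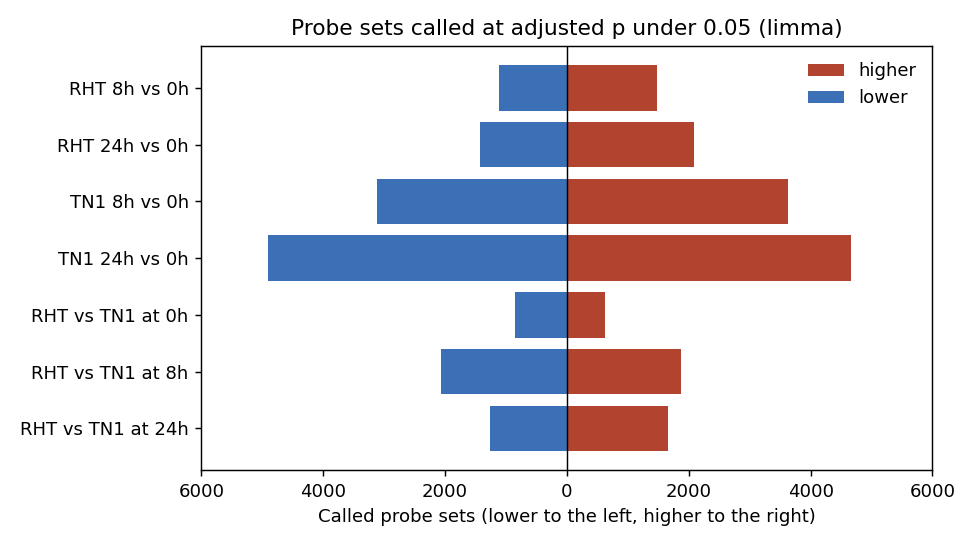
Number of probe sets called by limma at an adjusted p under 0.05 in 7 comparisons, with lower to the left of 0 and higher to the right. TN1 at 24 h had 4665 higher and 4913 lower.

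Before infestation the varieties differed in genes of several kinds. In RHT OC-X, a cystatin gene, was 4.29 ± 0.49 higher and CAD8C, of the cinnamyl alcohol dehydrogenase family, 3.19 ± 0.17 higher, and MADS26, a MADS-box factor gene above background on 2 of the 3 TN1 arrays, at least 8.7-fold higher (adjusted p = 1.01e-05). MAN7, an endo-mannanase gene, stood at -4.85 ± 0.27 in RHT against TN1, and the kinase gene WNK7, above background on 2 of the 3 RHT arrays, was at least 13.2-fold lower (adjusted p = 9.86e-05). Other probe sets of the same gene did not share several of the differences: FBA3 was at least 5.63-fold higher in RHT (adjusted p = 4.15e-08) but stood at -0.04 ± 0.24 on its brightest probe set. NPR3 was at least 10.8-fold lower (adjusted p = 3.44e-06) but stood at 0.04 ± 0.31 and -0.03 ± 0.34 on its 2 brighter probe sets, while another dim probe set, not above background on any RHT array, was called at least 3.48-fold lower (adjusted p = 0.00642). HSP18.0 was at least 4.77-fold lower (adjusted p = 3.64e-06) but at 0.13 ± 0.21, and TPP7 at least 8.4-fold lower (adjusted p = 5.1e-05) but at 0.05 ± 0.23. Each of these 4 was not above background on any array of the lower variety on the first probe set. For WNK7 the other probe set was called in the same direction, at least 6.26-fold lower.

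Limma called 1470 probe sets at 0 h, 625 higher and 845 lower in RHT, with 1311 fitted differences over 2-fold and 611 with only 1 variety above background. The count rose with array quality weights, chosen after seeing the data, and fell above the 75th percentile, as the closing section gives. None of the 21 lists was called by camera at 0 h (lowest adjusted p = 0.201, with 3 lists at an unadjusted p under 0.05), and of the 23 ribosomal, 12 photosynthesis and 7 clock genes none was called. In all, 976 probe sets differed in the same direction at all 3 times, 450 higher and 526 lower in RHT.

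After 8 h, camera called the chitinase list lower in RHT than in TN1. Of the 11 chitinase genes 4 were called lower and none higher (6 lower adjusted over the list alone), with a median of -1.63, or -1.47 with values raised to background (adjusted p = 0.00952, and adjusted p = 0.932 with an estimated correlation). At 0 h, when the list was not called, its mean difference was -0.54 and its median -0.33, or 0.02 with values raised to background. Cht5 stood at -2.32 ± 0.45 at 8 h, but was already lower in RHT at 0 h, at -1.72 ± 0.45, and at 24 h stood at -2.15 ± 0.45. The values that follow are for 8 h. NAS3 was 2.93 ± 0.29 higher in RHT and RCABP69 0.97 ± 0.20 higher, and MADS26 at least 27.5-fold higher (adjusted p = 4.6e-08), above background on 1 of the 3 TN1 arrays. The calmodulin-like gene CML16 stood at -4.22 ± 0.44, with a fitted difference of -3.66 ± 0.44 already at 0 h. LAC24, above background on 1 of the 3 RHT arrays, was at least 12.7-fold lower (adjusted p = 8.24e-05). Limma called 3929 probe sets, 1870 higher and 2059 lower, with 2930 fitted differences over 2-fold and 827 with only 1 variety above background. The count was 2576 without RHT 8 h replicate 1 and 1438 in a fit to the 6 arrays compared. TN1 8 h replicate 1 stood apart for the chitinases, and without it the mean difference of -1.83 was -0.97, and CH16, at -2.95 ± 0.72 with all arrays, was not called (adjusted p = 0.0601), nor without RHT 8 h replicate 1 (0.0732). The chitinase list was not called without TN1 8 h replicate 1 (adjusted p = 0.192), without a filter (0.0636) or above the 75th percentile (0.0664), and other splits called up to 4 lists. The called lists numbered 2 without RHT 8 h replicate 2 or TN1 8 h replicate 3, and 3 without RHT 8 h replicate 3 or TN1 8 h replicate 2.

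After 24 h, camera called the list of expansins and xyloglucan enzymes higher in RHT. Of 21 genes 4 were called higher, 1 lower and 16 not (8 and 1 adjusted over the list alone), with a median of 1.01 (adjusted p = 0.0135, and adjusted p = 0.932 with an estimated correlation). The mean difference of this list was already 0.37 at 0 h and 0.51 at 8 h, when it was not called. At 24 h EXLA3 was 1.30 ± 0.28 higher, while EXLA2 stood at -1.16 ± 0.21. JAZ8, of the family that represses jasmonate signalling, was at least 4.78-fold higher (adjusted p = 0.00147) and the nicotianamine synthase gene NAS2 at least 12.2-fold lower (adjusted p = 0.00399), each not above background on any array of the lower variety. OC-X was 6.05 ± 0.49 higher, and the potassium transporter gene HAK18 stood at -3.55 ± 0.27. Both differed in the same direction already at 0 h, with a fitted difference of -3 ± 0.27 for HAK18. Limma called 2920 probe sets, 1663 higher and 1257 lower, with 2294 fitted differences over 2-fold and 658 with only 1 variety above background. The count was 1818 without RHT 24 h replicate 3 and 1726 without TN1 24 h replicate 1. Without TN1 24 h replicate 1, which stood apart for this list, the mean difference of 1.14 was 0.82 and the list was still called. The list was not called without a filter (adjusted p = 0.12) or with all probe sets of a gene (0.0594), 2 lists were called without TN1 24 h replicate 2, and other splits called up to 4 lists.

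The difference between the responses of the varieties was tested directly. At 8 h limma called 8 probe sets, 4 higher and 4 lower in RHT minus TN1, and 3817 had an unadjusted p under 0.05. MAN7 rose by 1.53 ± 0.27 in RHT and fell by 1.92 ± 0.27 in TN1, a difference of 3.45 ± 0.39 (adjusted p = 0.00285). At 24 h 1 probe set was called and 2099 had an unadjusted p under 0.05. Camera called 0 lists at either time, with 5 lists at 8 h and 2 at 24 h at an unadjusted p under 0.05. At 8 h the count was 3 without RHT 0 h replicate 1 or 2, 5 without RHT 8 h replicate 1, 4 without TN1 0 h replicate 1, and 20 and 33 without TN1 8 h replicates 1 and 2. At 24 h it was 0 without most arrays, 6 without RHT 24 h replicate 2 and 7 without TN1 24 h replicate 2. With array quality weights, chosen after seeing the data, the counts were 2030 at 8 h and 170 at 24 h. The called lists at 8 h moved from 0 in 7 of 12 refits: to 1 without RHT 0 h replicate 3, RHT 8 h replicate 2 or TN1 8 h replicate 1, to 2 without RHT 8 h replicate 3 or TN1 8 h replicate 2 or 3, and to 3 without TN1 0 h replicate 3. At 24 h 1 list was called without RHT 24 h replicate 1 or TN1 24 h replicate 2.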

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

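The splits of the samples described here were run only after the result was seen. A direct test of the difference between the varieties' responses (RHT minus TN1) drew attention to 8 probe sets at 8 h and 1 at 24 h, because the effects differed between groups. Those without a published name fall outside the naming rule and are given because they were called.

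MAN7, an endo-mannanase gene, rose by 1.53 ± 0.27 in RHT and fell by 1.92 ± 0.27 in TN1 at 8 h, a difference of 3.45 ± 0.39 (adjusted p = 0.00285). It stayed called when any of 12 arrays was left out (highest adjusted p = 0.0167). LOC4335739, without a published name, fell by 1.02 ± 0.22 in RHT and by 3.96 ± 0.22 in TN1, a difference of 2.94 ± 0.31 (adjusted p = 0.00228, at most 0.0164 with an array left out). LOC4339947 fell by 2.72 ± 0.29 in TN1 and stood at 0.57 ± 0.29 in RHT, a difference of 3.29 ± 0.41 (adjusted p = 0.00652, at most 0.0357 with an array left out).

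The other differences were each lost in several of the 12 refits that left out an array. LOC4352758 differed by 3.21 ± 0.45 (adjusted p = 0.0234, lost in 5 refits), falling by 3.24 ± 0.32 in TN1. The transporter gene ABCG48 differed by -2.68 ± 0.40 (adjusted p = 0.0331, lost in 7) and the laccase gene LAC24 by -4.77 ± 0.74 (adjusted p = 0.0407, lost in 8), and ABCG48 rose by 1.99 ± 0.28 in TN1. LOC4346529 differed by -3.89 ± 0.59 and an unnamed probe set by -3.69 ± 0.56 (adjusted p = 0.0331 and lost in 8 refits for each). At 24 h an unnamed probe set differed by 3.96 ± 0.52 (adjusted p = 0.0367, lost in 10), a fitted size only, since it was not above background on any TN1 array at 24 h and the fall in TN1 was at least 1.93-fold. LAC24 and LOC4346529 were above background on 1 of the 3 TN1 arrays at 0 h, so their sizes are fitted as well, with rises in TN1 of at least 11.6-fold and 12.8-fold. LAC24 and the other unnamed probe set were above background on 1 of the 3 RHT arrays at 8 h and 2 of the 3 at 0 h, and that probe set on 2 of the 3 TN1 arrays at 0 h.

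Splitting the samples in other ways could not tell whether chance explains either count. Of 100 splits, 11 called at least the 8 probe sets of the real split at 8 h, with a highest count of 1491 among the others, and 14 called at least the 1 of the real split at 24 h, with a highest count of 5011. With array quality weights, chosen after seeing the data, the counts were 2030 and 170, so the number of such differences depends on how the arrays are weighted. The splits regrouped arrays by time within each variety, so a split can carry the time response common to both varieties into the contrast. Such splits are no measure of chance for these counts, and no conclusion was drawn from them.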

How the results depend on the processing

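With array quality weights, chosen after seeing the data, limma called 5747 (RHT 8 h), 8780 (RHT 24 h), 13256 (TN1 8 h), 7407 (varieties at 0 h) and 4623 (varieties at 24 h) probe sets, 2030 and 170 for the interaction at 8 h and 24 h, shared 3868 and 6747, with r = 0.547 at 24 h. The weights ran from 0.2 (TN1 8 h replicate 1) to 4.33 (TN1 0 h replicate 2). A fit to the compared arrays only called 3836 for TN1 at 8 h, 1438 for the varieties at 8 h, 3 for the interaction at 24 h, and 939 shared at 8 h. The interaction count at 8 h was 15 after quantile normalization. At 24 h it was 0 after quantile normalization, after median centring, with the offset, without a filter and above the 75th percentile, and 3 without a variance trend or, chosen after seeing the data, without RHT 0 h replicate 3 and TN1 8 h replicate 1. Above the 75th percentile the varieties at 0 h had 885 calls, with fewer probe sets tested. The correlation of responses was 0.3 at 8 h and 0.39 at 24 h without a filter, and 0.648 and 0.842 above the 75th percentile. With an estimated correlation camera called 0 lists in each of the 6 comparisons that had any. The varieties at 8 h had 0 lists without a filter, 0 above the 75th percentile and 2 with all probe sets of a gene. At 24 h they had 2 after quantile normalization, 0 without a filter and 0 with all probe sets, and each interaction had 1 list after quantile normalization. Except for smaller filters and fewer arrays, the cause was not tested.

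Leaving out each array in turn gave 1232 to 2678 calls for RHT at 8 h, 1700 to 2321 at 24 h, 4502 to 6855 for TN1 at 8 h and 6339 to 9025 at 24 h. The varieties had 1064 to 1389 at 0 h, 2576 to 3682 at 8 h and 1726 to 3282 at 24 h, and the interaction 3 to 33 at 8 h and 0 to 7 at 24 h. Called lists ranged from 1 to 2 (RHT 8 h), 1 to 1 (RHT 24 h), 2 to 5 (TN1 8 h), 1 to 1 (TN1 24 h), 0 to 0, 0 to 3 and 1 to 2 (varieties at 0, 8 and 24 h), and 0 to 3 and 0 to 1 (interaction). Shared calls ranged from 977 to 2417 at 8 h and 1508 to 3072 at 24 h, and r from 0.407 to 0.529 and 0.561 to 0.648. These fits hold fewer arrays.

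Among named genes, direction turned only for clock genes near 0 that were not called. Leaving out an array also turned the mean of some uncalled lists, such as mitotic cyclins in TN1 at 8 h (-0.19, and 0.71 without TN1 8 h replicate 1), and at 0 h between the varieties dehydrins (-0.41, and 0.17 without TN1 0 h replicate 2) and histone H2B (-0.12, and 0.49 without TN1 0 h replicate 3). PRR1 in RHT at 24 h was -0.02 after quantile normalization, 0 after median centring, -0.08 without RHT 0 h replicate 1 and -0.11 without RHT 24 h replicate 2 (range -0.11 to 0.15). PRR73 in RHT at 24 h was -0.01 after median centring and -0.05 without RHT 0 h replicate 2 (range -0.05 to 0.08), and PRR1 in TN1 at 24 h was 0.10 without TN1 24 h replicate 1 (range -0.4 to 0.10). Of 4343 log2 changes of named genes across settings 4030 kept direction and side of the threshold, 272 were weaker, 34 stronger and 7 turned. For list tests 106 of 120 kept their side and 14 were weaker. Camera offers no robust variance fit, so that alternative was not run for lists. Signal over background limits dim genes: between 24384 and 31462 rice probe sets per array lay above the brightest reporter tag.

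With the replicate number as a block the interaction had 4 calls at 8 h and 0 at 24 h, and no other count of calls, and no list count, moved by over 1.5 times. Of 249 changes followed for named genes and interaction calls, 11 lost their call under the block. Deviations of 45 same-numbered pairs correlated from -0.281 to 0.289, 11 of them over 0.1, and 8 of 18 arrays correlated best with their own number, so the numbers were not taken as pairs.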

Other observations

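The tests of time of day, array scaling and the actin difference, the relations within groups and the splits of the samples were chosen only after the result was seen. The bound for the clock genes was first a ratio of 0.5 with no allowance for error, which the TN1 ratio exceeded. The allowance of 2 standard errors was added after that value was known and turned the reading from argued against to open. The wider test of 8 h transcripts was first a combined test and was split by variety, with the same allowance, after its values were known. CM-LOX1, AOS2, JAZ11, CESA4, CESA7, CESA9, SWEET14, HSP17.9A, CAD3, NYC1, and LAC7 and RBTI at 8 h, were named after their values were seen.

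Jasmonate and cell wall genes were called in TN1 at 8 h. Of 17 jasmonate biosynthesis genes 5 were called higher in TN1 (7 adjusted over the list alone). The lipoxygenase gene CM-LOX1, above background on 2 of the 3 TN1 arrays at 0 h, was at least 9.45-fold higher in TN1 (adjusted p = 0.00139), and the allene oxide synthase gene AOS2 rose by 2.02 ± 0.46 in TN1. Of 13 JAZ and TIFY repressor genes 4 were called higher in TN1 (6 adjusted over the list alone), and JAZ11 was -3.02 ± 0.55 in RHT against TN1. Of 11 secondary wall genes 2 were called higher and 6 lower in TN1 at 8 h (3 and 7 adjusted over the list alone), with CESA7 lower by 1.14 ± 0.27. In RHT against TN1 at 8 h 5 were higher and 1 lower (5 and 3 adjusted over the list alone), with CESA4 at 1.19 ± 0.25 and CESA9 at 1.23 ± 0.28. The laccase gene LAC7 rose by 2.18 ± 0.40 in RHT and 3.67 ± 0.40 in TN1 at 8 h. TN1 8 h replicate 1 stood apart, with a jasmonate mean of 10.16 against 8.64 and 8.83 in replicates 2 and 3 and a JAZ mean of 11.55 against 9.42 and 10.03. Without it the mean rises of 1.48 and 1.06 were 1.00 and 0.46, and CM-LOX1, AOS2 and JAZ11 stayed called. These means use the deposited values. With values raised to background the medians in TN1 went from 1.12 to 0.51 for jasmonate and from 0.89 to 0.43 for JAZ. None of these lists was called in TN1 (adjusted p = 0.159 for jasmonate, 0.245 for JAZ and 0.361 for secondary wall), although jasmonate and JAZ were called without TN1 8 h replicate 2. None was called between the varieties at 8 h (0.171, 0.185 and 0.291) or for the interaction (0.262, 0.243 and 0.164), although without TN1 8 h replicate 2 jasmonate and JAZ were called between the varieties and JAZ for the interaction. Without replicate 1 the mean differences between the varieties shrank from -1.07 to -0.59 for jasmonate and from -0.87 to -0.26 for JAZ. In the interaction limma called 0 jasmonate and 0 JAZ genes and the secondary wall gene LAC24 (adjusted over the list alone, 3 jasmonate genes and 1 JAZ gene lower, and 5 secondary wall genes higher and 2 lower), with 3817 probe sets at an unadjusted p under 0.05.

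In TN1 at 8 h, of 20 phenylpropanoid genes 2 were called higher and 7 lower (4 and 9 adjusted over the list alone), and CAD3 fell by 3.03 ± 0.25, and by 1.73 ± 0.25 in RHT. Of 24 cytochrome P450 genes, which include allene oxide synthases, 8 were higher and 1 lower (8 and 1 adjusted over the list alone), of 6 WRKY genes 3 and 1 (5 and 1 adjusted over the list alone), and of 7 proteinase inhibitor genes 3 and 0 (3 and 0 adjusted over the list alone), with RBTI up by 4.01 ± 0.61. Of 12 diterpenoid genes 1 was higher (0 adjusted over the list alone), of 8 ethylene-responsive genes 1 higher (0 adjusted over the list alone), and of 6 glutathione S-transferase genes 1 lower (1 adjusted over the list alone). Of 4 chlorophyll breakdown genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone), and the chlorophyll b reductase gene NYC1 rose by 1.17 ± 0.20. Of 21 heat shock genes 1 was higher and 3 lower (1 and 3 adjusted over the list alone), with HSP17.9A up by 1.61 ± 0.27, and of 21 sugar transport and invertase genes 1 higher and 2 lower (1 and 2 adjusted over the list alone), with SWEET14 up by 1.79 ± 0.28 and in RHT by 1.69 ± 0.28. None of 7 dehydrin, 5 histone H2B and 7 mitotic cyclin genes was called (0 adjusted over the list alone), where limma gave 11105 probe sets an unadjusted p under 0.05. TN1 8 h replicate 1 stood apart here as well, at 11.77 against 10.65 and 10.65 for chlorophyll breakdown, 12.12 against 11.37 and 11.24 for proteinase inhibitors and 6.15 against 9.04 and 8.64 for mitotic cyclins. Without it their mean changes of 0.49, 0.77 and -0.19 were 0.11, 0.50 and 0.71, and NYC1 and RBTI stayed called. Camera called none of these lists. For the mitotic cyclins in RHT at 8 h the mean change was -1.98, and the median -2.2, or -1.37 with values raised to background. Their mean in RHT against TN1 at 8 h was -1.3, and -0.75 without TN1 8 h replicate 2. The list was not called in either comparison.

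The median size of the clock gene changes was smaller at 24 h than at 8 h in both varieties, which would fit a difference in time of day as well as an effect of feeding. In TN1, 2 of the 7 genes did not follow: PRR95 stood at -0.98 and then 1.12, and PRR73 at -0.20 and then 0.28. The median went from 1.22 to 0.41 in RHT, a ratio of 0.34 ± 0.097. In TN1 the median went from 1.31 to 0.7, a ratio of 0.535 ± 0.371, so that time of day remained open. The values after ± are jackknife standard errors here and for the ratios below. PCL1 was not above background at 0 h: with values raised to background the ratios were 0.238 and 0.271, and without PCL1 0.222 and 0.461, all lower and nearer to a return to 0 h. These were added after the first ratios were seen, so the reading was left open. Array scaling was argued against, since the sizes kept 1.021 of their value under other scalings. Transcripts called in RHT at 8 h, measured in TN1, kept a ratio of 0.482 ± 0.044 of the shift at 24 h. That was over the bound of 0.25 set for time of day as the cause but not over 0.5, the bound set against it. By those bounds time of day stayed open. Transcripts called in TN1 at 8 h, measured in RHT, kept 0.881 ± 0.162 (jackknife standard error), which argued against time of day as the whole cause.

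Ribosomal protein transcripts were lower at 24 h in both varieties, and RNA quality may mimic such a fall. The within-group slope on the actin difference was -0.094 ± 0.11, and the upper 95% bound of the share it explained was 0.29 in RHT and 0.13 in TN1. That argued against the measured actin difference as the main cause. The bounds took this difference as free of error and may be too low, so RNA quality itself was not settled. A fall of all bright probe sets was argued against: among 10000 random lists matched on signal none was as low, a percentile of 0 in each variety. Scaling was argued against, with 0.957 of the fall kept. The elongation factor difference, which moved with time, was not modelled.

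Transcripts that differed between the varieties at all 3 times could reflect probe sequence differences. Agreement meant the same sign and at least 0.5 of the size of the gene's largest called probe set. Other probe sets of the same genes agreed in this way for 66 of 192 (34.4%), against 436 of 627 (69.5%) for genes called at 24 h in both varieties. The gap was 35.2 percentage points (Fisher's exact test, two-sided, p = 5.38e-18), with genes that are not independent. The median sizes were 2.76 and 1.16, so the rule asked for larger changes in the variety genes, and part of the gap may come from it. With values raised to background the shares were 32.3% and 62.4% (30.1 points). Differing chromosome segments also fit: in the gene order of assembly ASM3414082v1, 51 neighbouring pairs differed, against a mean of 12.6 and a highest of 24 in 1000 shuffles (permutation of gene order, p = 0.001), although tandem copies could add pairs. The 24 h genes formed 296 pairs against 279.3.

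Other splits of the 6 arrays of a comparison, too few at 10 for a share under 0.05, gave fewer calls than the real split in each case, which alone was 1 of 10. Swapping arrays between groups also puts the real difference into the spread within groups. Where groups differ, fewer calls thus follow by design, and the counts do not measure chance. The real and highest other counts were 2595 and 6 (RHT 8 h), 3508 and 190 (RHT 24 h), 6745 and 37 (TN1 8 h), 9578 and 2 (TN1 24 h), 1470 and 39 (varieties at 0 h), 3929 and 8 (8 h) and 2920 and 2 (24 h). For called lists the real and highest other counts were 2 and 4 (RHT 8 h), 1 and 3 (RHT 24 h), 2 and 7 (TN1 8 h) and 1 and 6 (TN1 24 h). They were 1 and 4 between the varieties at 8 h and at 24 h. Counting the real split, 7, 10, 9 and 10 splits had at least as many lists, and 9 each between the varieties. Each other split still held part of the real difference, so a shifted list can be called in it. The list counts therefore do not weigh for or against chance.

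Within groups, over 18 arrays, the mean of the mitotic cyclins correlated with that of chitinases at r = -0.53 (p = 0.134, permutation within groups; rho = -0.47, p = 0.144), of JAZ genes at r = -0.50 (p = 0.194; rho = -0.26, p = 0.429) and of jasmonate genes at r = -0.60 (p = 0.0807; rho = -0.51, p = 0.122), with an adjusted p of 0.194 for each r. Without TN1 0 h replicate 3 and TN1 8 h replicate 1, the arrays farthest out, r was -0.32, -0.35 and -0.32.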
